A study of Mus musculus with 8 samples.

How the data were processed

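The deposited intensity values, 1 signal per probe set and array for 8 Affymetrix mouse arrays, were computed and scaled with MAS5 per the submitters' processing notes. The values are on a linear scale, and in each array the mean signal after trimming 2 percent at each end is 500, without centring of probe sets. The version of MAS5, its masking and detection calls are not stated. Per the labels' protocols, 6 µg of total RNA from pooled livers was used for each array.

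From there, 64 control probe sets were left out of 45101. Of the 45037 others, 34945 had 1 gene in the platform's gene table, 932 had several and 9160 were not listed. Signals were put on a log2 scale after adding 71, the lower quartile of all values, so that folds of weak genes are understated. A gene was read from its probe set with the highest mean, and kept where that mean log2 value was at least 8.24, the median of all probe sets. This left 12112 of 18193 genes. Probe sets whose names end in _s_at or _x_at can bind related RNAs, among them those of Saa2, Mt1, Inf2, Cyp2b10 and Gstm3. No gene coordinates were used.

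For averaged comparisons limma (3.58.1, R 4.3.3) fitted arm and day as additive terms, with 3 residual degrees of freedom, and moderated variances with a trend on mean expression. The difference in response between arms added an interaction of arm with TCPOBOP and left 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The p-values rest on the spread between the pools of different days, and no spread between animals could be measured. For a single day or a change from day 0 within an arm, genes changed at least 2-fold were counted and no p-value was computed. Medians of gene lists on a single day were placed among those of 10000 random lists matched on mean expression in 20 bins.

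There were 36 gene lists fixed before the data were examined. Of these, 33 had enough measured members to be tested, and the sex chromosome, cholangiocyte and erythroid lists, with 2 measured members each, were left out. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over the 33 lists. The comparisons, lists, alternative settings and the rule for naming genes were also chosen before the data were examined.

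Genes were named by this rule. For averaged comparisons they were the 10 highest and 10 lowest log2 differences among called genes, or, with none, the 3 of smallest p in each direction. For a single day they were the 8 largest increases and 8 largest decreases among genes whose higher signal reached the upper quartile of its array. From each list described, up to 4 members with the largest change in that comparison could be named. Met, Egfr, Hgf, Nr1i3, Cyp2b10, Ccnd1, Myc, Foxm1, Cdk1, Mki67 and Cdkn1a were always read. Unnamed gene models were skipped.

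The tests were tried on simulated data with the design's 8 arrays and 12112 genes, of which 200 were changed in each of 10 simulations. The comparison of arms recovered 21.8, 84.6, 99.8 and 100 percent of genes changed 1.5-, 2-, 4- and 8-fold, and 7.55 percent of its calls were false. The comparison of days recovered 11, 71.4, 97.6 and 98.4 percent, with 6.83 percent false. The interaction recovered 0, 2, 55.2 and 82.4 percent, with 9.35 percent false. For list medians on 1 day, 8.5 percent of 200 unshifted lists and 100 percent of lists shifted by 0.5 or 1 on the log2 scale lay outside the central 95 percent of random lists. Simulated genes varied independently. The correlation estimated within real lists between arms ran from -0.098 for heat shock to 0.86 for secreted hepatocyte proteins. Lists whose members vary together can lie outside more often without a shift.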

Results

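Gene expression was measured in mouse liver on 8 Affymetrix arrays, 1 for each of 2 arms on each of 4 days. The control arm was littermates with a floxed Met gene that received corn oil. Per the labels, the MET KO + EGFRi arm had lost Met through 5 injections of tamoxifen (100 µl at 10 mg/ml) that switched on Cre. This arm ate a diet with canertinib, an inhibitor of EGFR, aimed at 80 mg/kg per day. MET and EGFR are the receptors of hepatocyte growth factor and of epidermal growth factor. Both arms then received TCPOBOP by gavage at 3 mg/kg, and livers were taken on days 0, 1, 2 and 5. TCPOBOP activates the constitutive androstane receptor (CAR, encoded by Nr1i3) and makes mouse hepatocytes divide without injury. The comparisons ask what the combined loss of MET and EGFR signalling changes in the liver and in its response to this mitogen.

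RNA of the livers of a group was pooled and read on 1 array, so each of the 8 groups had 1 array and no replicate. The number of mice per pool, their sex, and whether the day 0 mice had received TCPOBOP are not given in the labels. The median signal over 45101 probe sets was 251, 238, 224 and 243 in the control arrays of days 0, 1, 2 and 5, and 239, 238, 235 and 241 in the MET KO + EGFRi arrays. Ratios of 3' to 5' actin probe sets ran from 1.57 to 2.36, the latter in MET KO + EGFRi at day 5. Cyp2b10, the best known CAR target, had a signal of 444 in control and 356 in MET KO + EGFRi at day 0, and of 32027 to 48292 in the other 6 arrays. Xist, transcribed in females, had a signal of 5970.4 to 9437, and Uty, on the Y chromosome, of 135 to 441. Each pool therefore held RNA of female livers. Of 4 listed sex chromosome genes with a probe set, only these 2 passed the filter, and whether males were also pooled is not settled. The number of arrays limits the precision of every value below.

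Averaged over the 4 days, the list with the largest median difference between the arms was that of acute phase proteins, with 13 of 24 members called higher in MET KO + EGFRi livers. On days 0, 1, 2 and 5, 24, 23, 24 and 22 members were higher. Among the called genes, Saa1, lipocalin 2 (Lcn2) and the metallothioneins Mt1 and Mt2 stood many times above control. The periportal enzyme Cyp2f2 was lower, as were the fatty acid synthesis and storage genes Elovl6, Fads2, Pnpla3 and Me1.

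Saa1 had a signal of 1046 to 2612 in the 4 control arrays and of 13192 to 56587 in the 4 MET KO + EGFRi arrays, a mean log2 difference of 4.32 with a standard error of 0.41 over the 4 days (adjusted p = 0.00533). Lcn2 ran from 525 to 911 in control and from 5470.1 to 36042 in MET KO + EGFRi (log2 difference 4.33, adjusted p = 0.00989). Saa2 rose most, by a log2 difference of 5.46 (adjusted p = 0.041), on a probe set that can bind its relatives. The metallothioneins Mt1 and Mt2 rose by 3.22 and 3.20, Serpina3n by 2.82 and Lrg1 by 2.66 on the log2 scale, with adjusted p of 0.0438, 0.0284, 0.0338 and 0.0139. Saa3 rose by 2.18 and the calgranulins S100a8 and S100a9 by 1.95 and 1.69, with adjusted p of 0.00533, 0.00224 and 0.00506. Lrg1, S100a8 and S100a9 are not members of the acute phase list. Mmd2, also outside that list, was near background in control, with signals of 79.1 to 118. It had 2594 to 4089 in MET KO + EGFRi (log2 difference 4.44, the smallest adjusted p at 4.07e-05). Since the control signals are near the pseudocount, this size depends on it, with 5.21 without a pseudocount and 3.51 with the median as pseudocount, and it was 3.05 with the mean of probe sets. Prtn3, a neutrophil protease, had 63.1 to 146 in control and 1033 to 1826 in MET KO + EGFRi (log2 difference 3.15, from 2.32 to 3.87 over the alternatives, adjusted p = 3.11e-04). The formin Inf2 had 1109.7 to 1422 and 5861 to 12458 (log2 difference 2.78, adjusted p = 4.72e-04). Smaller increases were seen for the peroxisomal enzyme Ehhadh (1.21), the urea cycle enzyme Asl (0.88), decorin Dcn (1.00) and the macrophage protein Cd5l (0.95), with adjusted p of 0.0213, 0.0298, 0.0298 and 0.0468. All genes of this paragraph were higher in MET KO + EGFRi on 4 of 4 days.

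Among the lower genes, Cyp2f2 had a signal of 20696 to 30518 in control and of 3117 to 5913 in MET KO + EGFRi (log2 difference -2.64, standard error 0.19, adjusted p = 0.00181). G0s2, an inhibitor of lipolysis, followed with -2.44 (adjusted p = 0.00533). The fatty acid elongase Elovl6 had a log2 difference of -1.79, the desaturase Fads2 of -1.21, Pnpla3 of -1.21 and malic enzyme Me1 of -0.98, with adjusted p of 0.019, 0.0179, 0.0422 and 0.0298. Insig1, which holds back cholesterol synthesis and is itself a target of its regulator, had -1.17 (adjusted p = 0.00989). The remaining named genes were Gsta4 (-1.84), Hao2 (-1.78), Prom1 (-1.72), Gprc5c (-1.37), Cpne7 (-1.33), carbonic anhydrase Car3 (-1.26) and Mup5 (-1.23), with adjusted p from 0.00573 for Prom1 to 0.0428 for Gsta4. All 14 genes of this paragraph were lower in MET KO + EGFRi on 4 of 4 days.

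limma called 70 of 12112 genes between the arms, 50 higher and 20 lower in MET KO + EGFRi. At an unadjusted p under 0.05 there were 741 higher and 725 lower. The test sets the mean difference of the 4 days against its spread between days, with 3 residual degrees of freedom. Leaving out 1 array gave 20 to 57 called genes, with 45 without the control and 41 without the MET KO + EGFRi array of day 0, 21 and 20 without those of day 1, and 40 and 39 without those of day 2. The array left alone on its day was fitted by that day's term and added nothing to the difference between arms. Both fits of a day therefore rest on the same other days and are not independent. Saa1, Saa3, S100a8, S100a9, Mmd2, Prtn3, Inf2, Cyp2f2, G0s2 and Prom1 stayed called in all 8 of these fits, and Lcn2, Lrg1, Insig1 and Gprc5c in 6. Serpina3n stayed called in 4, and Saa2, Mt1, Mt2, Ehhadh, Dcn, Elovl6, Fads2, Me1, Gsta4, Hao2 and Car3 in 2, while Asl, Cd5l, Pnpla3, Cpne7 and Mup5 stayed called in 0. Over 11 alternative settings Mt1 (adjusted p from 0.0231 to 0.153) and Cd5l were called in 4, Gsta4 in 5, Saa2 (0.0214 to 0.113), Serpina3n and Pnpla3 in 6, Dcn and Me1 in 8, Mt2, Ehhadh, Asl, Elovl6, Hao2 and Car3 in 9 and Saa3, Lrg1, Insig1, Prom1 and Mup5 in 10. Cpne7 was called in 8 of 9 and Gprc5c in 9 of 10 settings that gave a value, and the other genes named in all. The mean of probe sets gave a log2 difference of 0.51 for Dcn (adjusted p = 0.192), 2.23 for Mt1 and -0.97 for Gprc5c, and the median as pseudocount gave -0.86 for Cpne7.

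**Figure D1:**
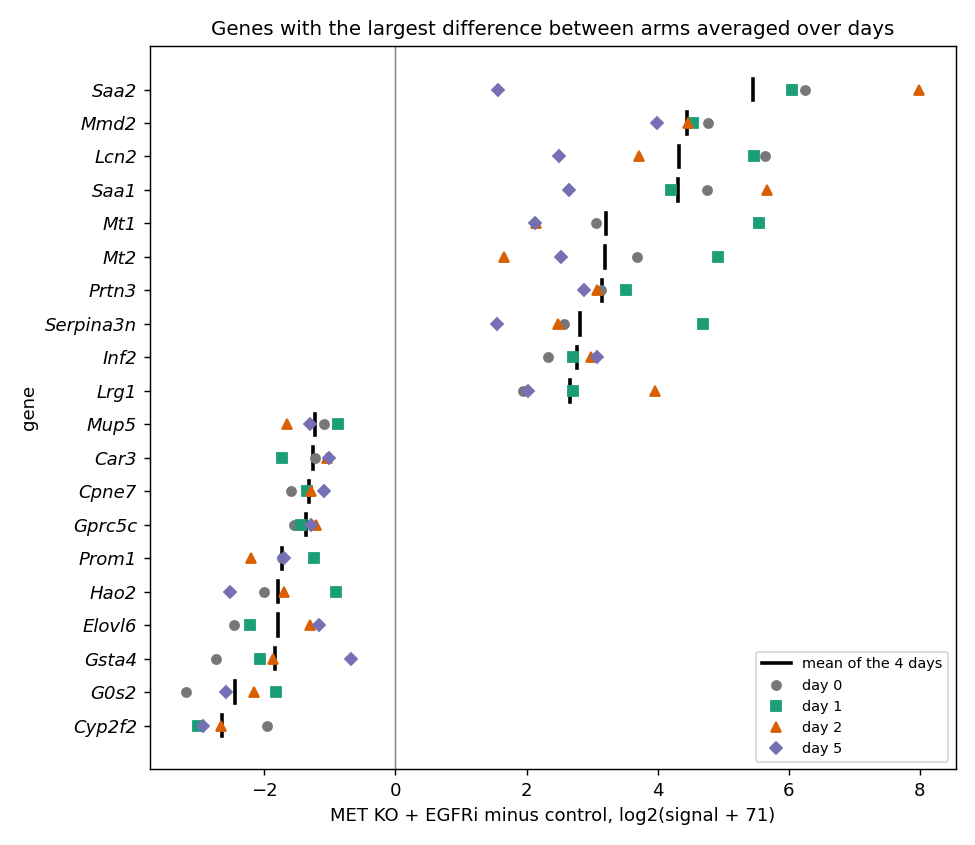
Difference between MET KO + EGFRi and control on each day for the 10 highest and 10 lowest genes among the 70 called, from -2.64 for Cyp2f2 to 5.46 for Saa2. The horizontal axis gives the difference in log2(signal + 71), each point is 1 day (1 array per arm), and the black bar is the mean of the 4 days.

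The acute phase list had all 24 measured members higher in MET KO + EGFRi, with a median log2 difference of 1.16. Of these, 13 were called over all genes and 22 adjusted over the list alone. limma's camera, which compares a list with the other genes under a preset correlation of 0.01, gave it an adjusted p of 2.22e-30, with adjusted p = 0.258 with an estimated correlation. limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes, gave 0.036. The monocyte and neutrophil list (median 0.41) had a camera adjusted p of 2.53e-06, with adjusted p = 0.258 with an estimated correlation, and 0.0224 in fry. It had 2 members called over all genes and 5 adjusted over the list alone. Kupffer cell and macrophage markers were higher for all 15 members (median 0.64, camera adjusted p = 3.49e-11, and adjusted p = 0.45 with an estimated correlation), with 1 called over all genes and 10 adjusted over the list alone.

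Fatty acid synthesis and lipid storage genes had a median of -0.68 (camera adjusted p = 3.49e-11, and adjusted p = 0.445 with an estimated correlation), and 0.179 in fry. Of its 21 members 4 were called lower over all genes, and adjusted over the list alone 15 were lower and 1 higher. Cholesterol synthesis genes had a median of -0.55 (camera adjusted p = 5.18e-11, and adjusted p = 0.45 with an estimated correlation), with 1 called lower over all genes and 12 adjusted over the list alone. CAR-induced phase I enzymes had -0.30 (7.06e-04, and adjusted p = 0.633 with an estimated correlation). CAR-induced phase II enzymes and transporters had -0.43 (8.51e-05, and adjusted p = 0.45 with an estimated correlation). G2/M and mitosis genes had -0.18 (0.00922, and adjusted p = 0.706 with an estimated correlation). Glucose production and amino acid catabolism had 0.21 (0.00183, and adjusted p = 0.633 with an estimated correlation).

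Those 9 of 33 lists were the ones camera called, 0 of which held with an estimated correlation. fry called 2, the acute phase and the monocyte and neutrophil lists, and 19 in its mixed form, which asks for change in either direction. The medians of the lists not called were 0.01 for hepatic nuclear receptors and transcription factors, -0.04 for G1/S regulators, -0.13 for DNA replication, 0.15 for CDK inhibitors and p53 targets, 0.15 for MET and EGFR receptors and ligands, 0.06 for ERK response genes and 0.16 for YAP targets and fetal genes. They were 0.11 for ribosome biogenesis, -0.01 for bile acid genes, -0.26 for fatty acid oxidation, 0.13 for secreted hepatocyte proteins, -0.06 for male-biased and -0.18 for female-biased liver genes, -0.21 for NRF2 targets, 0.11 for the unfolded protein response and -0.11 for heat shock. They were -0.03 for pericentral and 0.06 for periportal genes, 0.02 for the clock, 0.06 for lymphocyte, 0.13 for stellate cell, 0.02 for endothelial and -0.15 for pancreas, adipose and muscle markers, and -0.06 for reference genes. The periportal list's mean and test had the opposite sign to its median, since Cyp2f2 lay far below the other members.

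Several genes central to the question were read whether or not they were called. The Met probe set with the highest mean signal had 1444, 926, 1336 and 1149 in control and 1502, 1049, 2034 and 1358 in MET KO + EGFRi (log2 difference 0.26, adjusted p = 0.51). The other Met probe set had 786, 561, 359 and 531 in control and 639.5, 532, 650 and 389 in MET KO + EGFRi. The deleted exon is not given in the labels, so these signals say nothing about the knockout. Egfr had 3018, 3539, 3497 and 2766 in control and 4694, 4714, 3846 and 3336 in MET KO + EGFRi (log2 difference 0.36, adjusted p = 0.348), higher on 4 of 4 days. The mean difference was positive on all 6 Egfr probe sets kept by the filter, and largest, at 1.21, on one that had 2430, 2952, 1622 and 685 in control and 7694, 6844, 2537 and 1916 in MET KO + EGFRi. Hgf had 508, 224, 294 and 287 and 318, 481, 475 and 333 (log2 difference 0.27, adjusted p = 0.732). Nr1i3 had 3141, 2065, 1784 and 1887 in control and 1409, 863, 790 and 1709 in MET KO + EGFRi, lower on 4 of 4 days (log2 difference -0.89, adjusted p = 0.131). Cyclin D1, Ccnd1, had 4553, 6318, 6381 and 5647 and 1232, 3172, 3571 and 4264, lower on 4 of 4 days (log2 difference -1.01, adjusted p = 0.128). Its other probe sets had mean differences of -1.03 and -0.50, the latter with 494 in control and 704 in MET KO + EGFRi at day 5. None of these 5 genes passed the threshold.

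At day 0 the acute phase list already had a median above control, and the fatty acid synthesis list had its lowest median relative to control. The insulin-like growth factor binding protein Igfbp1, a gene induced by fasting and stress, had a signal of 839 in control and 14038 in MET KO + EGFRi. Saa2 (306 and 28584), Lcn2 (622 and 34565), Saa1, Mmd2 and Mt2 differed as strongly, as did the stress gene Gadd45g (165 and 3532) and the metalloreductase Steap4 (1680.2 and 20292). Lower genes were Rgs16 (2719 and 182), Rab3a (10518 and 1047), the glutathione transferases Gsta2 (2349 and 158) and Gsta4 (2009 and 241), Phgdh (2641 and 369), Igfbp2 (9223 and 1494), G0s2 and Elovl6. The fatty acid synthase Fasn had 12335 in control and 2629 in MET KO + EGFRi, Acly 14252 and 4361, and Pklr 6799 and 2063. The transcription factor gene Cebpb had 3883 and 9387. Only the MET KO + EGFRi arm ate the canertinib diet, and clock genes had a median absolute log2 difference of 0.50 between arms at day 0. Food intake and time of harvest were not tested as sources of the fatty acid gene differences.

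The acute phase list had a median log2 difference of 1.55 at day 0 (percentile 100 among 10000 random lists matched on mean expression), with 15 of 24 members at least 2-fold higher. Fatty acid synthesis had -0.85 (percentile 0, 9 of 21 at least 2-fold lower). The CAR-induced phase I and phase II lists had -0.44 and -0.38 (percentiles 0.07 and 0.08). Over all genes, 320 were at least 2-fold higher and 264 at least 2-fold lower. No p-value is given for a single day, since it rests on 1 array per arm. The percentiles here and below take the members of a list as independent.

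At day 1 the metallothioneins, Lcn2, Serpina3n and the serum amyloids were among the genes furthest above control, and the DNA replication list had a median below control. Mt1 had 843 in control and 42558 in MET KO + EGFRi, Mt2 978 and 31833, Serpina3n 1139.6 and 31110.3, Saa2 391 and 30385, and Lcn2 743 and 36042. Saa1, Mmd2 and Mroh2a (87.8 and 1834) completed the 8 largest increases. The major urinary protein gene Mup10 had 15723 and 1415, and Mup3 30231 and 3077. Rgs16, Serpina12, Cyp2f2, Setd4, Phgdh and the kinetochore gene Spc24 (869.8 and 63) were the other large decreases. Mcm2 had 1261 in control and 629.8 in MET KO + EGFRi, Mcm3 538 and 261, and Rrm2 3684 and 1967. Cdc20 had 1469.9 and 349.

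The DNA replication list had a median of -0.36 at day 1 (percentile 0), the G2/M and mitosis list -0.14 (percentile 2.81), cholesterol synthesis -0.67 (percentile 0), fatty acid synthesis -0.72 (percentile 0) and the acute phase list 1.00 (percentile 100). Kupffer cell and macrophage markers had 0.72 (percentile 100), with C1qb at 712 and 2063 and C1qa at 1183 and 2841. There were 350 genes at least 2-fold higher and 319 at least 2-fold lower, without a replicate.

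At day 2 the lists of mitosis and of cholesterol synthesis had their lowest medians relative to control, the latter and DNA replication having been lower at day 1 already. Mad2l1, a spindle checkpoint gene, had 1963 in control and 56.4 in MET KO + EGFRi. The mitotic cyclin Ccnb2 had 2030.4 and 163, Cdc20 2841 and 416, the cytokinesis gene Ect2 1076 and 116, Cdk1 1421 and 383, and Mki67 636 and 289. Ribonucleotide reductase Rrm2 had 3857 and 899.5, and Mcm2 1094 and 304. Foxm1 had 1199.8 and 922, on a probe set that changed little in control, with 1122, 959 and 1409 on days 0, 1 and 5. Its weaker probe sets, below the filter, went both ways at day 2. They had 248 and 233.6, 83.5 and 143.1, and 24.9 and 37.7. In the cholesterol pathway Msmo1 had 7993 and 1360.3, Idi1 6685 and 1479.9, Cyp51 3325 and 924, and Sqle 5825 and 1676. Mup10, Cyp2f2 and Prss8 (592 and 40.5) were the other large decreases. Saa2 (105 and 44381), Saa1, Mmd2, Nrip2 (50 and 2396), Lrg1, Lcn2, Prtn3 and Inf2 were the 8 largest increases.

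The G2/M and mitosis list had a median of -0.69 at day 2 (percentile 0), with 24 of 31 members lower and 9 at least 2-fold lower. The size of this median depended on the filter, since one at the upper quartile of the mean signal left 11 members with a median of -0.00598. That filter uses the mean over all arrays, and so also leaves out genes whose signal was high on only some days. Its median does not show that weak signals made the difference. Chosen instead by a signal at the upper quartile in an array of another day, 19 members had a median of -0.52 with a 95 percent interval from -1.12 to 0.01. DNA replication had -0.41 (percentile 0) and cholesterol synthesis -1.28 (percentile 0), with 12 of 19 members at least 2-fold lower. The acute phase list had 1.04 (percentile 100), Kupffer cell and macrophage markers 0.89 (percentile 100), and endothelial markers 0.48 (percentile 99.9). Glucose production and amino acid catabolism had 0.55 (percentile 100), and secreted hepatocyte proteins 0.57 (percentile 99.8, 16 of 16 higher). There were 349 genes at least 2-fold higher and 246 at least 2-fold lower.

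**Figure D2:**
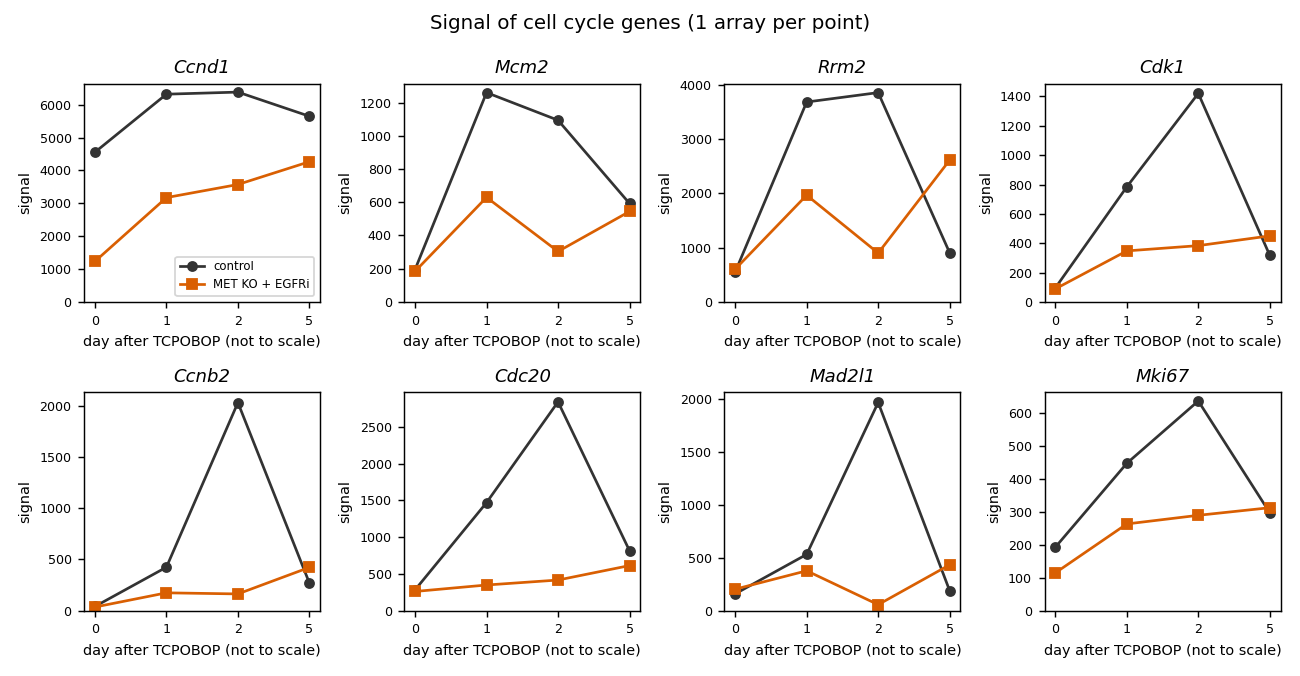
Signal of 8 cell cycle genes on days 0, 1, 2 and 5 in the control (black circles) and MET KO + EGFRi (orange squares) arrays, 1 array per point, with the vertical axis in signal from 0 and the days evenly spaced. Ccnb2, Cdc20, Mad2l1, Cdk1 and Mki67 had their highest control value at day 2, while Cdk1, Ccnb2, Mad2l1, Cdc20 and Mki67 had their highest MET KO + EGFRi value at day 5.

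At day 5 the median of the G2/M and mitosis list no longer lay below control, and Saa1 and Saa2 were closer to control but still above it. Ccnb2 had 269 in control and 422 in MET KO + EGFRi, Mad2l1 188 and 432, Cdk1 317 and 449.9, and Rrm2 905 and 2613. Saa1 had 2041 and 13192, and Saa2 427 and 1406. Estrogen sulfotransferase Sult1e1 had 476 and 3524, St3gal6 593 and 5614, and Mmd2, Inf2, Prtn3, Gprasp1 and Ttc7b were the other large increases. Hao2 had 7137 and 1182, Phgdh 5218 and 977, G0s2 1170 and 136, and Cyp2f2, Erdr1, Mrpl55, Nrip2 and Pou5f2 were the other large decreases.

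The G2/M and mitosis list had a median of 0.06 at day 5 (percentile 83) and DNA replication 0.22 (percentile 99.4). The acute phase list had 1.16 (percentile 100), cholesterol synthesis -0.35 (percentile 0.04), fatty acid synthesis -0.46 (percentile 0) and Kupffer cell and macrophage markers 0.50 (percentile 100). There were 272 genes at least 2-fold higher and 262 at least 2-fold lower. Over all 4 days, 29 genes were at least 2-fold higher and 8 at least 2-fold lower each day. Across genes, which are not independent replicates, Pearson's r between the differences of a pair of days ran from 0.0861 to 0.383.

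**Figure D3:**
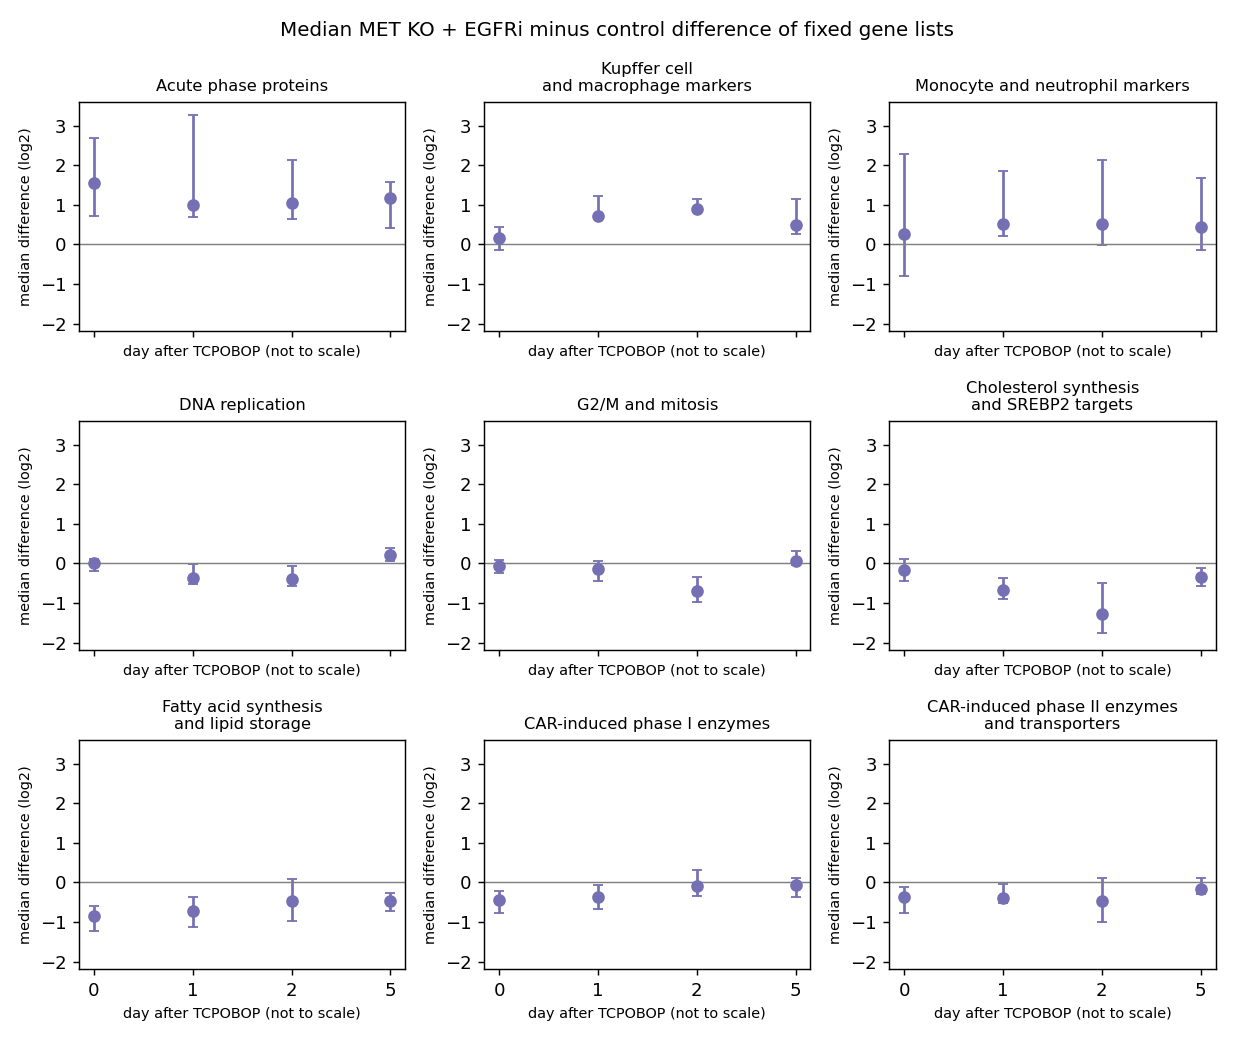
Median difference between MET KO + EGFRi and control, in log2(signal + 71), of 9 gene lists on each day (evenly spaced), with acute phase medians between 1.00 and 1.55 and the lowest cholesterol synthesis median at day 2, at -1.28. Points are medians over a list's measured members and bars their 95 percent intervals from order statistics, which take the members as independent and carry no spread between animals.

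Cyp2b10 and other drug metabolism genes of CAR rose after TCPOBOP, 9 of 17 phase I enzymes and 9 of 20 phase II enzymes and transporters being called.

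Averaged over arms and over days 1, 2 and 5, Cyp2b10 rose by 6.38 on the log2 scale (standard error 0.15, adjusted p = 1.37e-06), from 444 to 38898, 33939 and 45578 in control and from 356 to 37324, 32027 and 48292 in MET KO + EGFRi. Cyp2c55 rose by 5.16 (adjusted p = 3.13e-05), the carboxylesterase Ces2a by 3.62 (adjusted p = 6.23e-04), the pump Abcc4 by 3.17 (adjusted p = 0.00457) and Gstm3 by 3.06 (adjusted p = 5.09e-04). Abcc4 had a control signal of 26.1 at day 0, below the pseudocount, and its change was 4.35 without a pseudocount and 2.19 with the median as pseudocount. Smpd2 (2.51), the chemokine Ccl9 (2.41), Gstt3 (2.40), Prom1 (2.32) and Nebl (2.16) completed the 10 largest increases. Cyp1a2 rose by 1.99. Further CAR targets that rose, chosen after their values were seen, were Cyp2c54 (2.14), Cyp2c37 (1.69) and Aldh1a7 (1.34). The elongase Elovl3 rose by 1.62, the hepatokine Lect2 by 1.17 and carbonyl reductase Cbr1 by 1.29. Their adjusted p ran from 0.00457 for Prom1 to 0.0464 for Cbr1. Each of these genes was higher on days 1, 2 and 5 in both arms.

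Retinol dehydrogenases Rdh9 and Rdh16 fell by 2.49 and 1.53 on the log2 scale, with adjusted p of 0.0431 and 0.0351. Serpina4-ps1 had a log2 change of -2.24, the lipid chaperone Fabp5 of -1.69, Ugt3a1 of -1.40, Sppl2b of -1.29, the lysolipid transporter Mfsd2a of -1.27 and Gde1 of -0.99, with adjusted p from 0.0155 for Mfsd2a to 0.0464 for Sppl2b. Among the genes read in any case, the log2 change was 0.96 for Ccnd1, 1.89 for Cdk1, 0.96 for Mki67, 1.30 for Myc and -0.55 for Nr1i3, with adjusted p of 0.233, 0.11, 0.225, 0.247 and 0.466. None of these 5 passed the threshold.

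limma called 59 of 12112 genes, 51 higher and 8 lower after TCPOBOP, with 752 and 469 at an unadjusted p under 0.05. Day 0 rests on 1 array per arm. Without the control array of day 0, 1, 2 or 5 the count was 6, 10, 35 or 29, and without that of MET KO + EGFRi it was 4, 16, 49 or 12. Cyp2b10, Cyp2c55, Ces2a and Gstm3 stayed called in all 8 of these fits, Abcc4 and Prom1 in 6 and Ccl9 and Fabp5 in 5. Cyp2c54 stayed called in 4, Elovl3, Mfsd2a and Serpina4-ps1 in 3, Cyp2c37, Aldh1a7, Lect2, Cbr1, Rdh9 and Ugt3a1 in 2, Gstt3, Smpd2, Nebl and Cyp1a2 in 1, and Rdh16, Sppl2b and Gde1 in 0. Over 11 alternative settings Cbr1 was called in 4, Rdh9 in 5, Cyp1a2 and Smpd2 in 7, Gde1 in 8, Aldh1a7, Cyp2c37, Cyp2c54, Gstt3 and Serpina4-ps1 in 9 and Ccl9, Elovl3, Fabp5, Lect2, Mfsd2a and Prom1 in 10. Nebl was called in 4 of 9, Sppl2b in 4 of 10 and Rdh16 in 7 of 10 settings that gave a value, and the other genes named in all 11. With the median as pseudocount the log2 change was 1.54 for Nebl and -0.95 for Sppl2b.

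**Figure D4:**
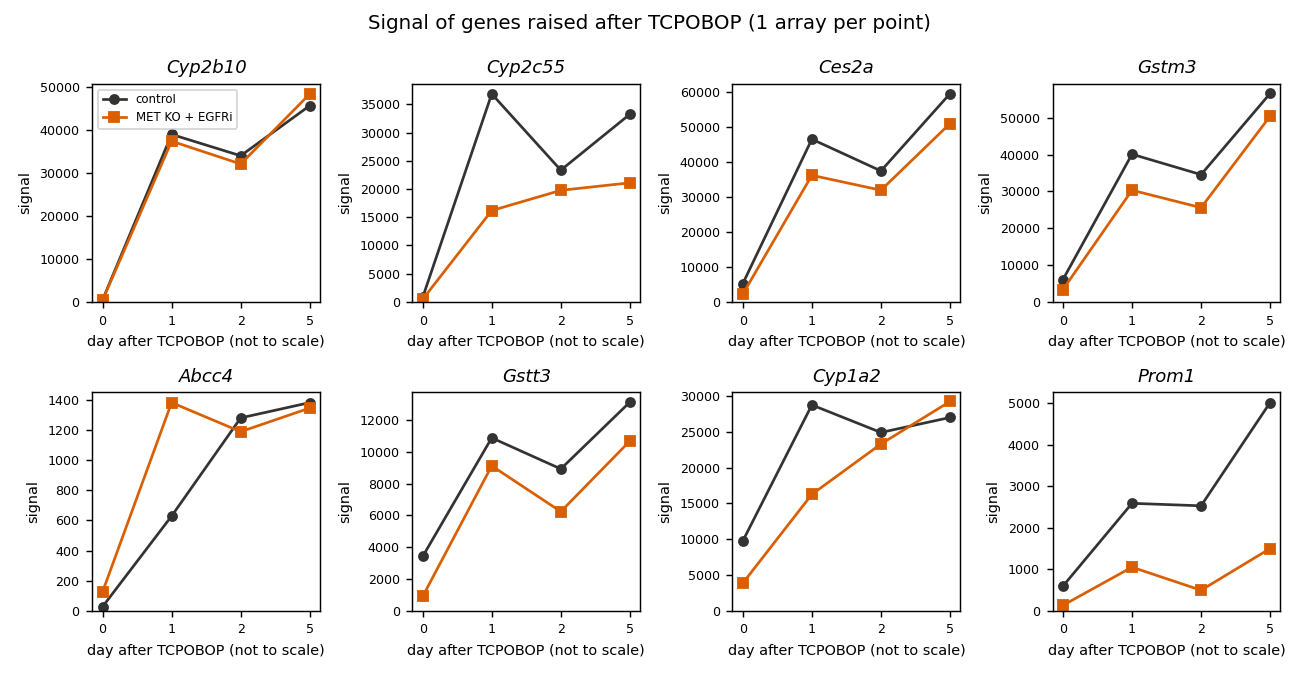
Signal of 8 genes that rose after TCPOBOP, on days 0, 1, 2 and 5 in the control (black circles) and MET KO + EGFRi (orange squares) arrays, 1 array per point, with the vertical axis in signal from 0 and the days evenly spaced. Cyp2b10 lies at 444 and 356 on day 0 and between 32027 and 48292 later, and Prom1 is lower in MET KO + EGFRi on each day.

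CAR-induced phase I enzymes had a median rise of 1.34, with 17 of 17 members higher, 9 called over all genes and 17 adjusted over the list alone (camera adjusted p = 3.20e-35, and adjusted p = 0.12 with an estimated correlation). Phase II enzymes and transporters had 1.31, with 20 of 20 higher, 9 called over all genes and 20 adjusted over the list alone (2.84e-34, and adjusted p = 0.12 with an estimated correlation). fry gave these lists adjusted p of 0.00981 and 0.0105 and called no other. The other lists called by camera were G2/M and mitosis (median 0.42, 6.89e-08, and adjusted p = 0.755 with an estimated correlation), secreted hepatocyte proteins (0.34, 1.65e-05, and 0.768 with an estimated correlation) and DNA replication (0.30, 1.53e-04, and 0.768 with an estimated correlation). They also included cholesterol synthesis (0.31, 0.00303, and 0.768 with an estimated correlation), NRF2 targets (0.23, 0.0122, and 0.553 with an estimated correlation) and fatty acid oxidation (-0.15, 0.0317, and 0.768 with an estimated correlation). The secreted protein list's median in control at day 5 became -0.0252 after quantile normalization, so its sign on that day depended on scaling between arrays. In the G2/M list 1 gene was called over all genes and 6 adjusted over the list alone. With an estimated correlation 0 of the 8 lists held, and fry's mixed form called 10. Among lists not called, median, mean and test differed in sign for the acute phase list (median -0.09, mean -0.21, camera and fry upward), CDK inhibitors and p53 targets, ribosome biogenesis, pericentral genes, the clock, and pancreas, adipose and muscle markers.

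In the control arm, the lists of DNA replication and of mitosis both had medians above day 0 on days 1 and 2. Mcm2 had 195, 1261, 1094 and 593 on days 0, 1, 2 and 5, Rrm2 551, 3684, 3857 and 905, Cdk1 95, 784, 1421 and 317, Ccnb2 40.7, 424, 2030.4 and 269 and Cdc20 283, 1469.9, 2841 and 816. Ccnd1 had 4553, 6318, 6381 and 5647 and Myc 36.4, 303, 459.9 and 149.8. The DNA replication list had medians of 0.57, 0.48 and 0.09 against day 0 (percentiles 100, 100 and 86.9), and G2/M and mitosis 0.47, 0.76 and 0.29 (percentiles 100, 100 and 100). With a filter at the upper quartile of the mean signal, which left 11 members, the G2/M and mitosis median at day 1 was -0.0153. CAR-induced phase I enzymes had 1.21, 1.11 and 1.46, and cholesterol synthesis 0.72, 0.33 and 0.44. Besides Cyp2b10, Cyp2c55, Ces2a, Abcc4, Smpd2, Gstm3 and Nebl, the largest increases held Cyp3a44 at day 1 (217 and 5544) and Cyp26a1 and Prss8 at day 5. Decreases held Rdh9 and Acot3 (6269.9 at day 0, 516 at day 1), Lrg1 at day 2 (7019.6 and 1196), and Serpina4-ps1, Slco1a1 and Usp2 at day 5. At least 2-fold higher and lower were 312 and 275 genes at day 1, 313 and 331 at day 2, and 342 and 311 at day 5.

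In the MET KO + EGFRi arm the lists of CAR-induced enzymes also had higher medians after TCPOBOP than at day 0, while the G2/M list's median was below that of control at day 2. Mcm2 had 184, 629.8, 304 and 545 on days 0, 1, 2 and 5, Rrm2 603, 1967, 899.5 and 2613, Cdk1 88.5, 348, 383 and 449.9, Ccnb2 35.1, 174, 163 and 422 and Cdc20 261, 349, 416 and 613. Ccnd1 had 1232, 3172, 3571 and 4264 and Myc 159, 254, 395 and 425. The DNA replication list had medians of 0.32, 0.15 and 0.23 against day 0 (percentiles 100, 97.9 and 99.6), and G2/M and mitosis 0.35, 0.11 and 0.51 (percentiles 100, 93.5 and 100). CAR-induced phase I enzymes had 1.34, 1.43 and 1.89, and cholesterol synthesis 0.31, -0.60 and 0.18. Kupffer cell and macrophage markers had -0.02, 0.60 and 0.61, against -0.65, -0.27 and 0.26 in control. Large increases were Cyp2b10, Cyp2c55, Ces2a, Cyp2c29, Gstm3, Gstt3, Sult1e1 and Cnmd. Large decreases were Gadd45g (3532 at day 0, 447 at day 1), Igfbp1 (14038 and 2327), Ppp1r3c (2805 and 80), Steap4 at day 2, and Saa2 and Mup3 at day 5. At least 2-fold higher and lower were 194 and 213 genes at day 1, 258 and 253 at day 2, and 342 and 327 at day 5. Comparisons within an arm share its day 0 array. Cdkn1a had 684, 634, 743 and 712 in control and 1132, 723, 648 and 786 in MET KO + EGFRi. Its other probe set, below the filter, differed more between arms. It had 49.8, 79.1, 184.3 and 214.5 in control and 1244.6, 169.1, 55.7 and 51.5 in MET KO + EGFRi.

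The last comparison asks whether the arms' responses to TCPOBOP differed. No single gene passed the threshold. The genes with the smallest p were the repair gene Ercc1, which had 837, 546, 675 and 208 in control and 236, 2601, 2218 and 529 in MET KO + EGFRi (difference of log2 changes 3.18, adjusted p = 0.568), Polr2a (1.96, 0.568) and Rgs3 (2.13, 0.568). In the other direction were Tab1 (-3.38, 0.51), the interferon response gene Rtp4 (-2.98, 0.568) and the sterol hydroxylase Cyp7b1 (-2.43, 0.568). Cyp2b10 had a difference of 0.25, Cyp2c55 of -0.01, Ces2a of 0.93, Ccnd1 of 1.09, Cdk1 of -0.72, Ccnb2 of -1.14 and Cdc20 of -1.52.

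limma called 0 of 12112 genes here, with 251 higher and 292 lower at an unadjusted p under 0.05, and 0 in each alternative setting run. The fit has 2 residual degrees of freedom. On simulated data it recovered 2 percent of genes changed 2-fold and 82.4 percent of those changed 8-fold, so a gene whose response differed 2-fold would mostly have been missed. camera called 8 lists. They were Kupffer cell and macrophage markers (median 0.67, 8.49e-06), fatty acid synthesis (0.53, 0.00165), cholesterol synthesis (-0.57, 0.00619), the acute phase list (-0.28, 0.00621), the unfolded protein response (-0.25, 0.0215), male-biased liver genes (-0.24, 0.0353), CAR-induced phase I enzymes (0.25, 0.0353) and endothelial markers (0.35, 0.0476). All 8 had adjusted p = 0.931 with an estimated correlation, and fry called 0 in either form. The G2/M and mitosis list had a median of -0.25 (camera adjusted p = 0.171). Median, mean and test differed in sign for hepatic nuclear receptors, bile acid genes, fatty acid oxidation, NRF2 targets and reference genes, none of them called. Across genes, which are not independent replicates, Pearson's r between the arms' changes from day 0 was 0.269 on day 1, 0.113 on day 2 and 0.313 on day 5. On these days 109, 89 and 148 genes changed at least 2-fold in the same direction in both arms.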

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

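Chosen only after the result was seen were the tests of neutrophil or monocyte RNA, of tamoxifen, canertinib or Cre, of mitosis genes chosen on other days, of a later rise of mitosis genes, of harvest time and of food intake.

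A pair of results stood out because the arms moved in opposite directions on all 3 days after TCPOBOP. Male-biased liver genes had median log2 changes of 0.46, 0.38 and 0.32 in control on days 1, 2 and 5 and of -0.12, -0.21 and -0.08 in MET KO + EGFRi, a mean difference of -0.52. Their interaction had a camera adjusted p of 0.0353, and 0.931 with an estimated correlation. Hgf changed by -0.97, -0.67 and -0.70 in control and by 0.51, 0.49 and 0.06 in MET KO + EGFRi, a mean difference of 1.13. This rests on 1 of 3 probe sets, the only one kept by the filter. Of the weaker ones, 1 had 103, 93.3, 123 and 135 in control on days 0, 1, 2 and 5 and 209.7, 251, 266 and 99.1 in MET KO + EGFRi, which does not show the pattern. For Hgf as a single gene the interaction had an adjusted p of 0.999. These were 2 of 33 lists and 11 genes examined, and in simulations 12.5 percent of unchanged items moved apart in this way. The rule itself is no test of the difference. With 1 array per group, no search for an array far from others of its group was possible.

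The acute phase list had a median above control in MET KO + EGFRi on 4 of 4 days, with 24, 23, 24 and 22 of 24 members higher. After quantile normalization the lowest of the 4 daily medians was 0.87, which argues against scaling between arrays as the cause. RNA of neutrophils or monocytes in the livers cannot be told apart from a response of the liver's own cells. Of 8 markers 2, S100a8 and S100a9, were at least 2-fold higher on all 4 days and the other markers were not. Prtn3, a neutrophil gene outside that list, was higher by 3.14, 3.51, 3.07 and 2.87 on the log2 scale. It was named for its large difference in these data, so it is no independent marker of neutrophils here. Tamoxifen, canertinib or Cre acting apart from the loss of MET and EGFR signalling cannot be told apart from that loss, because 0 control arrays received tamoxifen or canertinib. A response of hepatocytes to the lost signals may therefore be 1 of several sources.

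The G2/M and mitosis list had a median of -0.69 between MET KO + EGFRi and control at day 2, with 24 of 31 members lower, and of -0.00598 over the 11 members left by a filter at the upper quartile. The median was -0.70 after quantile normalization, which argues against scaling between arrays. A median of -0.79 over the 27 members whose higher day 2 signal reached the upper quartile does not bear on noise of low signals, since those members were chosen on the compared signals. Among random lists matched on mean expression, the list's median at day 2 lay at percentile 0. This argues against noise of low signals that is independent between genes, for the 31 members as a set. Noise shared by members was not tested. The median of 19 members chosen on other days was -0.52 with a 95 percent interval from -1.12 to 0.01. It was -0.48 over 18 members high in control at day 1, and 0.01 over 9 with a high median over other days. A high mean or median over arrays also leaves out genes high on only some days. The sets of 11 and 9 members therefore cannot tell noise from a real difference, and the interval of the 19 members left both open. A block of division cannot be told apart from a later rise, since the list's median in MET KO + EGFRi at day 5 was 0.51 above its day 0 and 0 days were sampled between days 2 and 5.

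The cholesterol synthesis list had a median of -1.28 between MET KO + EGFRi and control at day 2. The median was -1.22 after quantile normalization, which argues against scaling between arrays. Harvest at another time of day cannot be told apart from it, because clock genes had median absolute differences of 0.50, 0.53, 0.33 and 0.78 on days 0, 1, 2 and 5 and cholesterol genes of 0.37, 0.67, 1.28 and 0.35, so that the former were 25.9 percent of the latter at day 2 but not on the other days. Lower food intake cannot be told apart from an effect on the pathway, because targets of the fasting regulator PPARA had a median of 0.0436 over 21 members that went both ways. Loss of MET and EGFR signalling, the drug diet and feeding may each contribute.

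The arms' count of 70 called genes was set against other splits of the arrays that keep 1 array of each day in each group. The highest of the others gave 0, and 8 splits are too few for a share under 0.05. Without a day term, the real split of 4 against 4 arrays gave 49 and the highest of the other splits, out of 35, gave 4. Chance can be excluded for that count only if arrays of different days are interchangeable, which the matching by day does not allow for. The split with 4 had both day 0 arrays and the MET KO + EGFRi arrays of days 1 and 2 in 1 group.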

How the results depend on the processing

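Every alternative was chosen before the data were examined, and no test in this part was chosen only after the result was seen. Under 11 alternatives the arms differed in 28 to 90 genes against 70 reported. The count was 28 (21 higher, 7 lower) without a filter on low signals, where more genes are tested, and within 1.5 times of 70 in the other 10. Changes after TCPOBOP were called in 13 to 84 genes against 59. The count was 26 without a filter, 35 with the mean of a gene's probe sets, 34 without a variance trend and 13 without an arm term. The cause was not tested for the last 3. The interaction had 0 calls in every setting run. Leaving out 1 array gave 20 to 57 genes between arms, with 45 and 41 without the control and the MET KO + EGFRi array of day 0, 21 and 20 without those of day 1, and 40 and 39 without those of day 2. After TCPOBOP it gave 4 to 49, with 6, 10, 35 and 29 without the control array of days 0, 1, 2 and 5, and 4, 16 and 12 without that of MET KO + EGFRi on days 0, 1 and 5. The interaction gave 0 to 0 in 6 such fits, and could not be estimated without either day 0 array. Between arms and in the interaction, an array without its partner adds nothing to the estimate, so both fits of a day rest on the same other days. In the comparison after TCPOBOP such an array still counts and is assumed to vary like the others.

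Of the lists camera called, 9 between arms, 8 after TCPOBOP and 8 in the interaction, an estimated correlation left 0, 0 and 0, and fry called 2, 2 and 0. After quantile normalization camera called 10, 11 and 8.

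Counts of genes changed at least 2-fold between the arms on days 0, 1, 2 and 5 became 322, 380, 300 and 251 with the median signal as pseudocount, 1103, 1233, 1190 and 1224 without a filter, 312, 317, 293 and 204 with a filter at the upper quartile, and 386, 437, 381 and 338 with the mean of probe sets. With every probe set on its own they were 935 on day 2 and 869 on day 5. At 1.5-fold they were 1890, 2048, 2184 and 1870. In control on days 1, 2 and 5 the same alternatives gave 319, 337 and 358, then 1150, 1266 and 1339, then 290, 335 and 328, then 369, 392 and 407, then 1020 on day 2 and 1033 on day 5, and 1976, 2257 and 2183. In MET KO + EGFRi they gave 195, 288 and 382, then 850, 1036 and 1268, then 198, 263 and 352, then 244 and 335 on days 1 and 2, then 612 and 788 on days 1 and 2, and 1419, 1810 and 2051. By construction, a larger pseudocount shrinks the folds of weak genes, a stricter filter removes such genes, and no filter adds them. The cause was not tested for the mean of probe sets.

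Of 2640 list medians under the alternatives, 2601 moved by less than their spread, 35 moved by more and 4 were counted as changing sign. A change of sign was counted only for lists that stood out from the random lists at first. Sign changes of other lists are included in the counts of medians inside or outside the interval. With a filter at the upper quartile, the G2/M and mitosis median was -0.00598 at day 2 between arms and -0.0153 in control at day 1, over 11 members. Secreted hepatocyte proteins had -0.0252 in control at day 5 after quantile normalization. Female-biased liver genes had 0.023 between arms at day 2 with every probe set on its own and 0.133 with the mean of probe sets. The cause was not tested. With the mean of probe sets, Ercc1 had -0.173 between arms at day 5 and St3gal6 -0.0708 in control at day 2, and the cause was not tested. Of 3929 tests of named genes under the processing alternatives 3791 kept their side of the threshold, 128 no longer passed it and 10 newly did. Direction was compared only for genes called in the main fit, and 0 of these tests reversed. With 1 array left out, 255 of 2794 such tests no longer passed it and 22 newly did. The totals of 3929 and 2794 include tests that had not passed at first and so could not be lost. The losses set against these totals therefore understate the share of calls that were lost. Scaling the arrays to the same median moved the median of all genes by 0.15 in control at day 2 against day 0, and neither scaling moved it by more than 0.1 in another comparison. Relative to the median of all genes, that day's median was 0.81 before and 0.81 after scaling for G2/M and mitosis, 0.52 and 0.51 for DNA replication, and 1.15 and 1.17 for CAR-induced phase I enzymes. With signals near 71 folds are understated, and arrays of 1 pool each give no spread between animals.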

Other observations

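No test in this part was chosen only after the result was seen. The signal of the Cre spike-in probe set ran from 13727 to 26435 over the 8 arrays. It was lowest at day 0, with 13727 in control and 16498 in MET KO + EGFRi, and 17270 or more on later days. At day 2 it had 17296 in control and 21561 in MET KO + EGFRi. Whether other strong signals, such as those of secreted proteins, shifted with it was not tested. Spearman's rho between pairs of arrays, across probe sets that are not independent replicates, ran from 0.872 to 0.93. Errfi1, a gene that EGFR signalling induces, had 22993, 19679, 12621 and 8104 in control and 34379.9, 24926, 28124 and 24705 in MET KO + EGFRi on days 0, 1, 2 and 5. The clock gene Dbp had 5908, 4935, 5226 and 1639.7 in control and 1278, 1799, 5211 and 3025 in MET KO + EGFRi on those days. Lists too small to test had these averaged log2 differences between MET KO + EGFRi and control: -0.24 for Epcam and 0.03 for Sox9 among cholangiocyte markers, -0.12 for Alas2 and 0.78 for Car2 among erythroid genes, and 0.29 for Xist and -0.03 for Uty, with adjusted p of 0.51, 0.97, 0.835, 0.103, 0.415 and 0.971 in limma.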
